A study of Mus musculus with 16 samples.

How the data were processed

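RNA from mouse soleus muscle was measured on Agilent 1-colour whole-genome arrays before hypoxia (day 0) and at days 3, 7 and 14 of a protocol that lowered the oxygen level gradually during the first week and then held it. The labels give 16 arrays from 14 RNA samples: 4 RNA samples at day 0, 3 at day 3, 3 at day 7 and 4 at day 14. All of them were used. The design text names 4 per day, and any further day 3 or day 7 sample was not analysed here. The labels do not say whether each RNA sample came from a separate mouse, nor at what time of day muscles were taken. The arrays lie on 2 slides with 1 scan each. Slide 1 carries the day 3 and day 7 arrays and day 0 RNA samples 1 and 2. Slide 2 carries the day 14 arrays and all 4 day 0 RNA samples, so day 0 RNA samples 1 and 2 were run on both slides.

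The deposited scanner files give, per the file headers, spot brightness as a linear intensity from Agilent Feature Extraction, with the local background subtracted and spatial trends removed, and with no scaling between arrays. The deposited series table also holds a linear intensity. Its columns have near-equal means and equal maxima, as after quantile normalization, and their medians lie between 45.1 and 46.4. Its ranks correlate with the median spot brightness at 0.986 to 0.996 across spots and with the background-subtracted intensity at 0.918 to 0.978. The steps that made it are not stated, and it served only as an alternative.

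Each array has 62976 spots, 59305 of them not controls. Spots well above background made up 48.3 to 55.3% of the non-control spots on slide 1 and 37.9 to 42.9% on slide 2. The 75th percentile of the intensity was 203 to 271 on slide 1 and 49.1 to 77.0 on slide 2. On slide 2 all day 14 arrays were dimmer than all day 0 arrays, at 49.1 to 67.11 against 67.14 to 77.0. Their spots well above background made up 37.9 to 38.9%, against 39.4 to 42.9% on those day 0 arrays. No spot was saturated, and 99 to 179 spots per array carried an outlier mark and were left out. For arrays, the number of RNA samples limits the precision.

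The background-subtracted intensity was put on the log2 scale, reduced by the 75th percentile of the non-control spots of the array, and averaged over the spots of a probe. Of 55681 probes, 37 had no value left on at least 1 array and were left out. Probes were named through RefSeq transcripts: 27656 (49.7%) received the symbol of 1 of 20972 genes, and 28025 kept their array name. The array design refers to an older assembly than the annotation, so no coordinates are given. Probes well above background on at least 3 of the 16 arrays were kept (29479), and the probe with the highest mean stood for its gene, which left 22145 features, 14107 of them named genes. Where no array of a group was above background, a fold is given as a bound against the background level of the arrays, or left out where that bound was under 1. Where only some arrays of a group were above background, the fitted difference is printed, and values near background limit its size.

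Days were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), by its moderated statistic, 2-sided. The model had day and slide as fixed terms and the RNA sample as a random block, so that an RNA sample run on both slides counted as 1 replicate. The correlation of arrays of 1 RNA sample was 0.448, with 11 residual and 2.45 prior degrees of freedom. Differences are given as log2 values, later day minus earlier day, with the standard error (SE). Values per day are means over RNA samples with the standard deviation (SD). P-values were adjusted by Benjamini-Hochberg over all 22145 features in each comparison, and a feature passed at an adjusted p under 0.05. A moderated F-test covered the 3 differences from day 0. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.

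The comparisons, the tests, 33 gene lists (metabolic and stress pathways, fibre types, cell states and markers of other cell types) and the rule for named genes were fixed before the data were examined. The rule took, for each day against day 0, the 8 largest rises and the 8 largest falls among features past the threshold that were well above background on every array of at least 1 group, had no overlap between the days after slide adjustment, and had a gene symbol. It took 5 in each direction for day 7 against day 3 and for day 14 against day 7, up to 2 in each direction per list (if none passed, the 2 with the smallest p), the 6 features with the smallest p of the F-test, and 20 core genes of hypoxia, fibre type and metabolism. From these, 115 genes were selected for the text after the values were seen, with preference for genes called under 3 treatments of the slide. Some genes are not reported here. Lists were tested with limma's camera at a preset correlation of 0.01, after removal of the array correlation, and adjusted over the 33 lists in each comparison. Camera with an estimated correlation and fry were run beside it, and the members of a list were also adjusted over the list alone. The plan named list tests for the 3 differences from day 0 only, and those between later days were run in the same way. Lists share members, and muscle fibres express some genes of the marker lists.

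The procedure was tested on simulated data with the same design and 22145 features. It recovered 11.9 to 31.8% of changes of 0.5 log2 against day 0, 50.7 to 67.2% of changes of 1 log2 and 81.8 to 98.5% of changes of 2 log2, with 0.952 to 5.04% of calls false. For day 14 against day 7, 7.58% of calls were false. Outside 1 raised list, 66 or 67 features were changed at each size and later day against day 0. In the data 1349 and 5263 features passed at days 3 and 7. Recovery and the false share depend on how many features change, so these rates may not hold there. A raised list was called at an adjusted p of 2.84e-31, and 0 of 30 unchanged lists were called. Noise was drawn for each feature on its own, so genes of a simulated list were not correlated. The list result therefore says nothing about false calls of lists whose genes are correlated. The simulation had the same slide difference on all arrays of a slide, so it says nothing about arrays that depart from their slide.

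Alternatives were: no slide term with the arrays of 1 RNA sample averaged, each slide alone, the replicate number as a block, normexp background correction with an offset of 50, quantile normalization, median scaling, the series table, no filter on dim probes, probes above background on all arrays, the mean of the probes of a gene, limma with trend and robust options, only the days compared, and leaving out each RNA sample. The files hold no mean spot brightness, so normexp used the median brightness of the spot and of its background. An alternative without the slide 1 arrays of day 0, and the set of genes called in 1 direction with the slide term, without it and without those arrays, were chosen after seeing the data.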

Results

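Gene expression in the mouse soleus, a hindlimb muscle rich in slow fibres, was measured before and during a gradual reduction of the oxygen level. Day 0 had 4 RNA samples on 6 arrays, day 3 had 3, day 7 had 3 and day 14 had 4, for 16 arrays on 2 slides. Between 22502 and 32782 spots per array were well above background, with the higher numbers on slide 1. On the first principal component, which held 35.4% of the variance, the 2 day 0 arrays on slide 1 scored -39.3 and -42.2. The day 3 and day 7 arrays on the same slide scored -19.7 to 9.40, and the same 2 RNA samples on slide 2 scored -0.551 and 4.27. The slide differences of these 2 RNA samples had a correlation of 0.811 across 14803 features, which are not independent replicates. Every comparison of slide 1 days with day 0, and of day 14 with day 7, rests on these arrays.

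**Figure D1:**
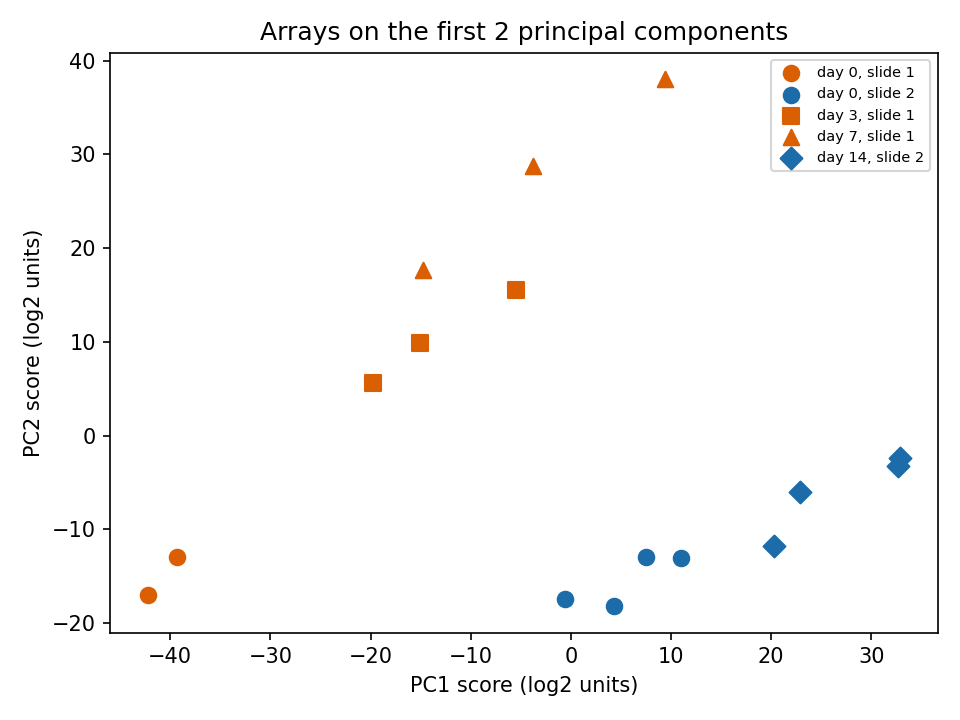
Scores of the 16 arrays on the first 2 principal components (log2 units), with 1 point per array, shaped by day and coloured by slide. The 2 day 0 arrays on slide 1 sit at -39.3 and -42.2 on the first component, left of all other arrays.

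Day 3 against day 0 asks what had changed while oxygen was still being lowered. Dbp, a clock-controlled transcription factor, fell by 2.30 ± 0.35 on the log2 scale (SE, n = 3 and 4, adjusted p = 0.00801), and Per3, a gene of the circadian clock, fell by 1.05 ± 0.28. Igfbp2, which encodes a binding protein for insulin-like growth factors, fell by 1.52 ± 0.28 (adjusted p = 0.0154), and Rnu3b1, a small nucleolar RNA, fell by 1.49 ± 0.26. Cd209f, a C-type lectin gene, rose by 1.55 ± 0.23 (adjusted p = 0.00801), Il1rl1, the receptor for interleukin 33, by 1.92 ± 0.38 (adjusted p = 0.0192), and Amd2, an enzyme of polyamine synthesis, by 1.16 ± 0.20 (adjusted p = 0.013). Slc22a2, an organic cation transporter gene, was at least 1.34-fold higher, since no day 0 array was above background (adjusted p = 0.0304). Mmp3, which encodes a matrix metalloproteinase, rose from a level below background on all 6 day 0 arrays (adjusted p = 0.00801). For each of these genes, all 3 day 3 samples lay beyond all 4 day 0 samples after slide adjustment. The rule for the largest rises and falls required this, so it adds no evidence for genes chosen by that rule. The slide adjustment itself rests on day 0 RNA samples 1 and 2.

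Among the lists at day 3, red blood cell and erythroid genes were lower, with 4 of 17 measured members past the threshold, 0 higher and 4 lower (8 lower and 2 higher adjusted over the list alone). Their median was -0.31 (camera, adjusted p = 0.00736, and adjusted p = 0.927 with an estimated correlation, range over 29 alternatives 0.000685 to 0.927). Adipocyte markers had a median of 0.45, with 1 of 23 members higher (3 adjusted over the list alone, adjusted p = 0.0255, and adjusted p = 0.975 with an estimated correlation, range 9.91e-05 to 0.975). Slow fibre genes had a median of -0.30, with 3 of 17 lower (8 adjusted over the list alone, adjusted p = 0.00202, and adjusted p = 0.927 with an estimated correlation, range 0.000189 to 0.927). Cytosolic ribosomal proteins had a median of 0.25, with 4 of 60 higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.000339, and adjusted p = 0.975 with an estimated correlation, range 1e-07 to 0.975). Beside the slow fibre genes, the fast fibre genes Myh4 and Pvalb lay at 9.52 to 9.85 and 7.30 to 8.57 in the day 3 samples, above the highest day 0 samples of 6.94 and 6.92, but did not pass (5.16 ± 1.57 and 1.69 ± 0.51, adjusted p = 0.0684 and 0.0651), and the fast fibre list did not pass either (median 0.08, adjusted p = 0.868). The slow fibre call ended without the slide 1 arrays of day 0 (adjusted p = 0.241), and the ribosomal call ended there (adjusted p = 0.597) and without the slide term (adjusted p = 0.0825). Hypoxia-inducible factor targets had 0 higher and 1 lower of 30 members (0 and 0 adjusted over the list alone), and their list did not pass (adjusted p = 0.894). The other 27 lists did not pass either. Of the called members of the red blood cell, adipocyte, slow fibre and ribosomal lists, 0 were called under all 3 slide treatments.

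At day 3, 1349 of 22145 features passed, 503 higher and 846 lower, and 190 of them differed at least 2-fold. Of the 1349, 92 (6.82%) were called in the same direction under all 3 treatments of the slide, 44 higher and 48 lower, and 421 turned sign in at least 1 of the other treatments. Without the slide 1 arrays of day 0, day 3 and day 0 lie on different slides, and that treatment cannot tell day from slide. The count was 504 without the slide term, 2075 without the slide 1 arrays of day 0, and 0 by limma within slide 1 alone, where 4559 features had an unadjusted p below 0.05. It was 16 without day 0 RNA sample 1, 4 without day 0 RNA sample 2, 788 without day 3 RNA sample 1, 139 without day 3 RNA sample 2 and 898 without day 7 RNA sample 1. Of the 12 selected genes called under all 3 slide treatments, 3 passed without day 0 RNA sample 1, 0 without day 0 RNA sample 2, 10 without day 3 RNA sample 1, 9 without day 3 RNA sample 2 and 11 or 12 without any other. None turned sign in any leave-out, but neither did any of the 1349, so this does not set these genes apart. Of the called features, 37.3% were higher, against 24.6% without the slide term and also without the slide 1 arrays of day 0, 47.5% after normexp correction and 48.8% with probes above background on all arrays.

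**Figure D2:**
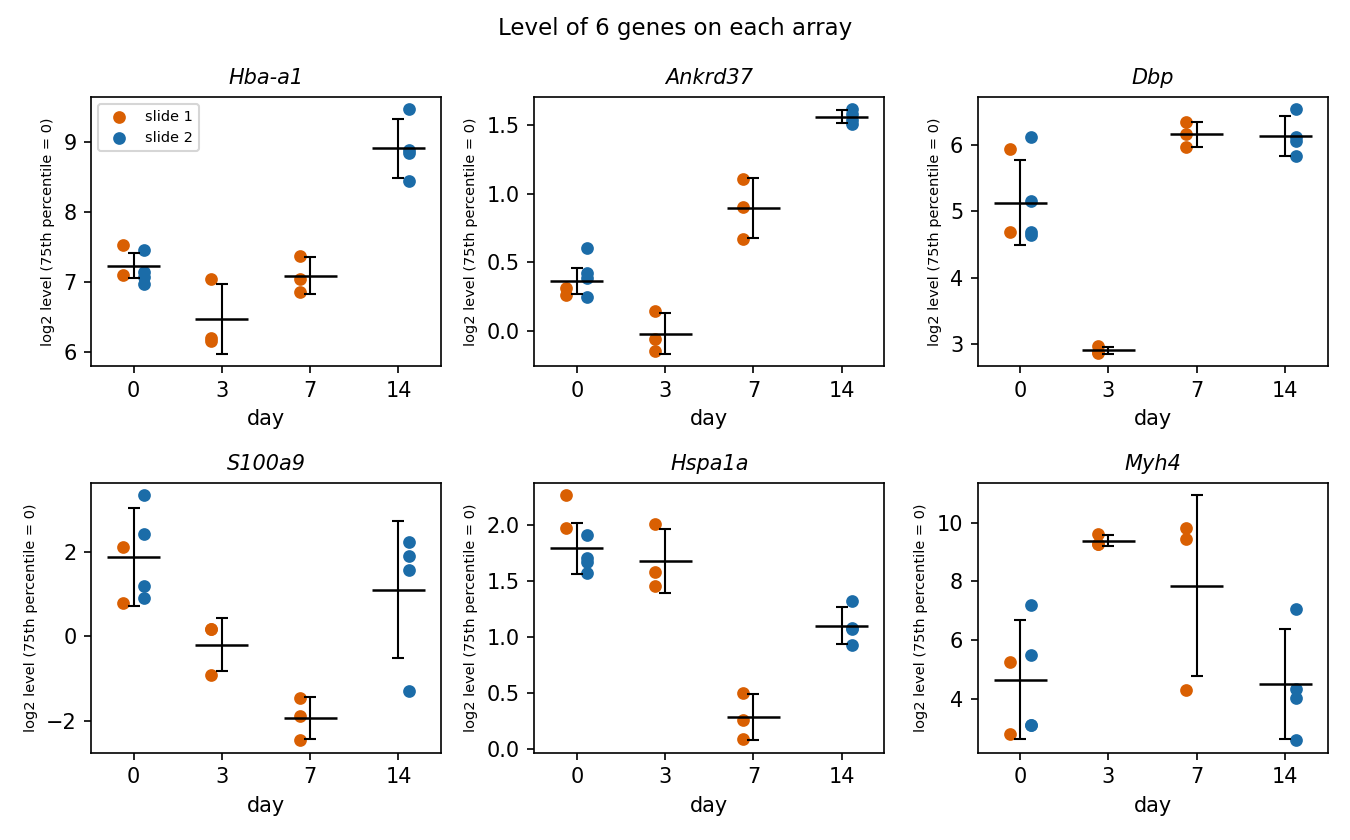
Log2 level relative to the 75th percentile of the array for 6 genes by day, with 1 point per array coloured by slide and not adjusted for slide, a bar at the mean over RNA samples and an error of 1 SD. Hba-a1 lies at 8.43 to 9.47 on the day 14 arrays and at 6.97 to 7.53 on the day 0 arrays.

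Day 7 against day 0 covers the end of the stepwise lowering of oxygen. Hspa1a, an inducible heat shock protein gene, fell by 1.79 ± 0.17 (adjusted p = 0.000471), and Ankrd2, a muscle protein that responds to stretch, fell by 1.25 ± 0.15 (adjusted p = 0.00142). The neutrophil genes S100a9 and S100a8 fell by 3.47 ± 0.89 and 3.04 ± 0.81 (adjusted p = 0.0145 and 0.0176). S100a8 lay at -4.54 to -2.92 at day 7. The lowest level counted as above background on these arrays was -3.64 to -3.35 before slide adjustment, so the size for S100a8 is uncertain. Pfkfb3, which makes an activator of glycolysis and is a target of hypoxia-inducible factor, rose by 1.49 ± 0.34 (adjusted p = 0.0082), and Ankrd37, another hypoxia-inducible factor target, by 0.64 ± 0.13 (adjusted p = 0.0062). Vldlr, a lipoprotein receptor gene, rose 2.15-fold (adjusted p = 0.00176). Tfrc, the transferrin receptor gene and also on the list of hypoxia-inducible factor targets, fell by 1.63 ± 0.28 (adjusted p = 0.00348).

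The selected genes of the major urinary protein family, Mup1, Mup17, Mup18 and Mup19, also fell at day 7. Members of this family are near-identical in sequence, so their probes may carry a shared signal, and the family was not tested as a list. Mup1 was at least 7.10-fold lower, as no day 7 array was above background (adjusted p = 0.00186), and Mup17, Mup18 and Mup19 fell by 3.48, 3.32 and 2.41. At day 7, Mup17 lay at -5.17 to -3.37 and Mup18 at -3.71 to -2.72, near or below background, so their sizes are uncertain. Wnt4, a secreted signalling protein, rose by 1.52, Angpt2, an angiopoietin, by 0.95, and Trib3, a stress-induced pseudokinase, by 0.90. Pvalb, the calcium buffer of fast fibres, rose by 1.65 ± 0.51 (adjusted p = 0.0319). Among glycogen genes, Pgm1 rose by 0.79 and Ppp1r3c fell by 1.05. Amd2 rose by 1.25, and the clock genes Cry2 and Tef by 1.01 and 0.99. Slc22a2 was at least 1.56-fold, Cdyl2 at least 1.36-fold and Pla2g5 at least 1.22-fold higher than at day 0, where they were below background on all arrays. Pcm1, a centrosome protein gene, rose by 1.71 ± 0.16, but its other kept probe had a difference of -1.38. For each gene named in these 2 paragraphs on day 7, all 3 day 7 samples lay beyond all 4 day 0 samples after slide adjustment. As at day 3, the rule required this of the largest rises and falls, and the adjustment rests on day 0 RNA samples 1 and 2.

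Genes of the mitochondrial respiratory chain were among those that rose at day 7. Of 76 measured members of oxidative phosphorylation, 30 were higher and 0 lower (36 and 1 adjusted over the list alone), and the median was 0.37 (camera, adjusted p = 1.36e-06, and adjusted p = 0.953 with an estimated correlation, range over 29 alternatives 6.96e-11 to 0.953). Atp5l was among them with 0.91 ± 0.14. Fatty acid uptake and oxidation had 11 higher and 1 lower of 34 (13 and 2 adjusted over the list alone), among them Decr1 with 1.07 ± 0.24 (list adjusted p = 0.00997, and adjusted p = 0.953 with an estimated correlation, range 0.000273 to 0.953). Cytosolic ribosomal proteins had 28 higher and 0 lower of 60 (34 and 2 adjusted over the list alone, adjusted p = 2.67e-06, and adjusted p = 0.953 with an estimated correlation, range 7.75e-10 to 0.953). Proteasome subunits had 14 higher and 1 lower of 31 (15 and 1 adjusted over the list alone, adjusted p = 0.00997, and adjusted p = 0.953 with an estimated correlation, range 0.000386 to 0.953). Under all 3 slide treatments 3 of the 30 higher members of oxidative phosphorylation passed, 1 of the 11 of fatty acid uptake and oxidation, 2 of the 28 of the ribosomal list and 1 of the 14 of the proteasome list.

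Macrophage, neutrophil and some structural lists had members that were lower at day 7, while lymphocyte and antigen presentation genes did not pass (median -0.17, adjusted p = 0.584). Macrophage and monocyte markers had 7 of 26 members lower and 0 higher (8 and 0 adjusted over the list alone), with C1qb at -1.53 ± 0.36 and a median of -0.79 (adjusted p = 4e-06, and adjusted p = 0.953 with an estimated correlation, range 1.74e-09 to 0.953). Neutrophil markers had 3 lower and 1 higher of 7 (4 and 1 adjusted over the list alone, adjusted p = 0.0392, and adjusted p = 0.953 with an estimated correlation, range 0.00798 to 0.953). Heat shock genes had 7 lower and 1 higher of 24 (9 and 1 adjusted over the list alone), with Hspb7 at -1.29 (adjusted p = 0.0012, and adjusted p = 0.886 with an estimated correlation, range 2.58e-05 to 0.886). Extracellular matrix and fibroblast genes had 7 lower and 1 higher of 34 (8 and 1 adjusted over the list alone, adjusted p = 0.00348, and adjusted p = 0.953 with an estimated correlation, range 9.19e-05 to 0.953). Slow fibre genes had 8 lower and 1 higher of 17 (10 and 2 adjusted over the list alone), with Myl6b at -1.14 (adjusted p = 0.00164, and adjusted p = 0.953 with an estimated correlation, range 2.98e-05 to 0.953). That call ended without the slide 1 arrays of day 0 (adjusted p = 0.0776). The fast fibre list did not pass (median 0.23, adjusted p = 0.558), and Myh4 ranged from 4.56 to 10.1 over the day 7 samples (adjusted p = 0.113). Satellite cell and myogenic genes had 3 lower of 24 (3 adjusted over the list alone, adjusted p = 0.0355, and adjusted p = 0.953 with an estimated correlation, range 0.00993 to 0.953), a call that ended without the slide term (adjusted p = 0.127) and without the slide 1 arrays of day 0 (adjusted p = 0.282). Hypoxia-inducible factor targets had 8 higher and 1 lower of 30 (8 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.68). Under all 3 slide treatments 2 of the 7 lower macrophage markers passed, 3 of the 3 neutrophil markers, 3 of the 7 heat shock genes, 3 of the 7 matrix genes, 4 of the 8 slow fibre genes and 0 of the 3 satellite cell genes. None of the other 20 lists passed.

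At day 7, 5263 features passed, 3458 higher and 1805 lower, and 695 of them differed at least 2-fold, 259 higher and 436 lower. Of the 5263, 1276 (24.2%) were called in the same direction under all 3 slide treatments, 905 higher and 371 lower, and 671 turned sign in at least 1 of the others. As at day 3, the treatment without the slide 1 arrays of day 0 cannot tell day from slide. The count was 2665 without the slide term, 2093 within slide 1 alone and 3878 without the slide 1 arrays of day 0, where the balance turned to 1652 higher and 2226 lower. It was 2028 without day 0 RNA sample 1, 25 without day 0 RNA sample 2, 3327 without day 7 RNA sample 1 and 2621 without day 7 RNA sample 2. Of the 45 selected genes called under all 3 slide treatments, 31 passed without day 0 RNA sample 1, 5 without day 0 RNA sample 2, 43 without day 7 RNA sample 1, 38 without day 7 RNA sample 2 and 43 without day 7 RNA sample 4. None turned sign, but neither did any of the 5263, so this does not set these genes apart.

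**Figure D3:**
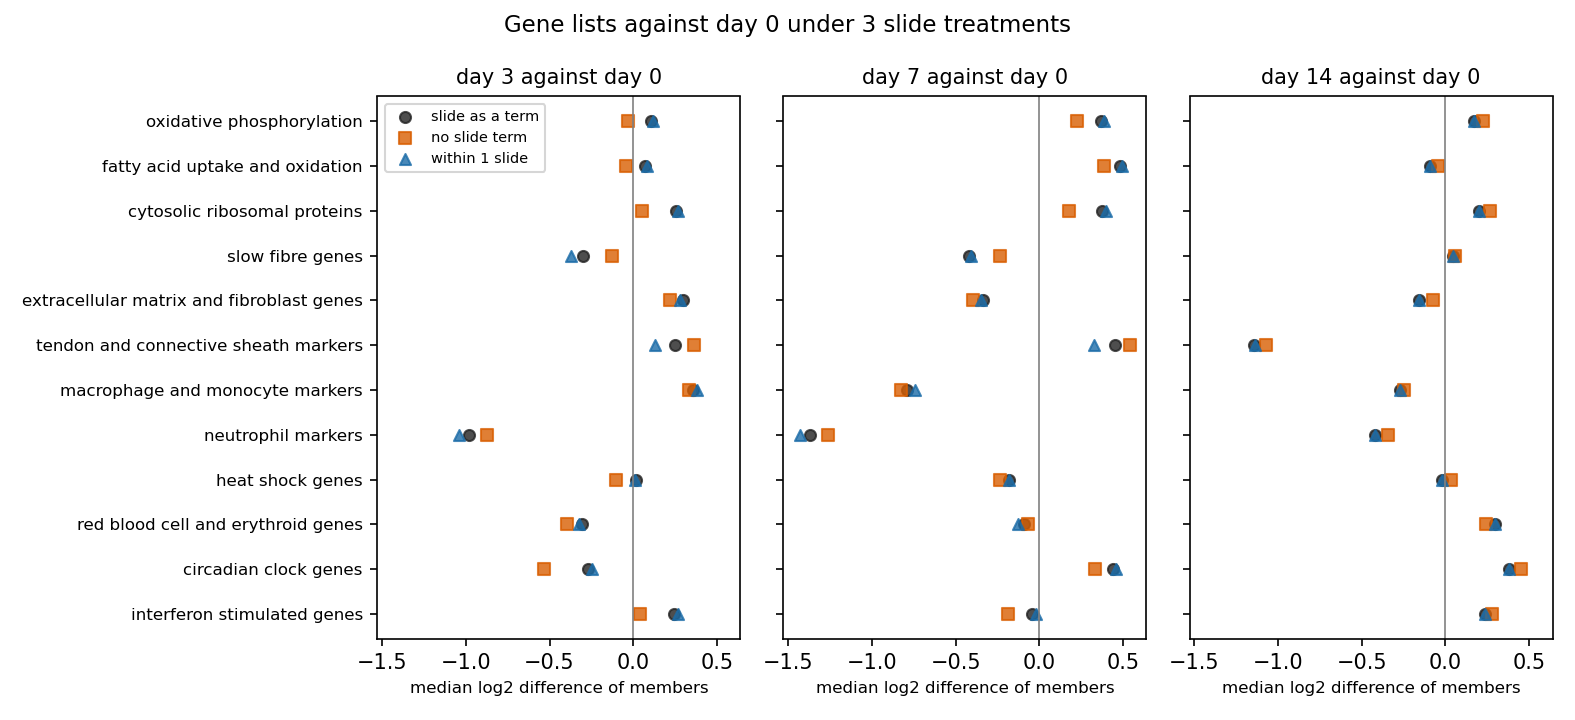
Median log2 difference from day 0 of 12 gene lists at days 3, 7 and 14, with the slide term, without it, and within 1 slide. Oxidative phosphorylation is at 0.37, 0.22 and 0.38 at day 7 under these 3 treatments.

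Day 14 against day 0 asks what differed after a further week at a stable oxygen level. The haemoglobin genes Hbb-bt, Hbb-b2 and Hba-a1 rose by 1.83 ± 0.24, 1.75 ± 0.25 and 1.74 ± 0.24 (n = 4 and 4, limma adjusted p = 0.0105, 0.0122 and 0.0105), and Alas2, the erythroid enzyme that starts haem synthesis, rose by 1.73 ± 0.25 (adjusted p = 0.0122). Ankrd37 rose by 1.14 ± 0.11 (adjusted p = 0.00139). Higd1b, a pericyte marker, rose by 0.81 ± 0.11 (adjusted p = 0.0105), and Ramp2, a receptor partner found in endothelial cells, by 0.63 ± 0.09 (adjusted p = 0.0158). Tent5c, a poly(A) polymerase, rose by 1.64, the amino acid transporter Slc6a20a by 1.48, and Zdhhc22, a palmitoyltransferase gene, 2.84-fold. Paqr7, a membrane progestin receptor, fell by 0.66, Lpcat3, an enzyme of phospholipid remodelling, by 0.70, and Sgsm3 by 0.79. For each of these genes all 4 day 14 samples lay beyond all 4 day 0 samples, which the rule required of the largest rises and falls. Fmod, a proteoglycan of tendon, fell by 2.07 ± 0.39 (adjusted p = 0.0447), with 3 of 4 day 14 samples below all day 0 samples, and this call was not kept under all 3 slide treatments.

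Red blood cell and erythroid genes had 6 of 17 members higher and 0 lower at day 14 (9 and 1 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.000441, and adjusted p = 0.753 with an estimated correlation, range over 29 alternatives 6.9e-06 to 0.753). Tendon and connective sheath markers had a median of -1.14 with 1 of 11 lower (5 adjusted over the list alone, adjusted p = 1.66e-05, and adjusted p = 0.753 with an estimated correlation, range 2.16e-10 to 0.753). Endothelial cell markers had 2 of 24 higher (11 higher and 2 lower adjusted over the list alone), with a median of 0.28 (adjusted p = 0.0275, and adjusted p = 0.753 with an estimated correlation, range 0.0101 to 0.753). That call ended without the slide term (adjusted p = 0.117) and within slide 2 (adjusted p = 0.0578). Under all 3 slide treatments 5 of the 6 red blood cell genes, 0 of the 1 tendon gene and 1 of the 2 endothelial genes passed. The following lists passed at day 14 without a member past the threshold. Interferon stimulated genes had a median of 0.23 (9 of 31 higher adjusted over the list alone, adjusted p = 0.000447, and adjusted p = 0.753 with an estimated correlation, range 0.000112 to 0.753). Circadian clock genes had a median of 0.38 (6 of 17 higher adjusted over the list alone, adjusted p = 0.0237, and adjusted p = 0.753 with an estimated correlation, range 0.00161 to 0.753).

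Cytosolic ribosomal proteins had a median of 0.20 at day 14 (0 of 60 adjusted over the list alone, adjusted p = 2.45e-07, and adjusted p = 0.753 with an estimated correlation, range over 29 alternatives 1.33e-08 to 0.753). Oxidative phosphorylation had a median of 0.17 (0 of 76 adjusted over the list alone, adjusted p = 0.000249, and adjusted p = 0.836 with an estimated correlation, range 2.34e-06 to 0.886), and its camera direction turned after normexp correction, where the median was 0.03. Macrophage and monocyte markers had a median of -0.27 (0 of 26 adjusted over the list alone, adjusted p = 0.0103, and adjusted p = 0.836 with an estimated correlation, range 4.63e-05 to 0.836). Extracellular matrix and fibroblast genes had a median of -0.16 (1 of 34 lower adjusted over the list alone, adjusted p = 0.0104, and adjusted p = 0.836 with an estimated correlation, range 1.74e-06 to 0.836). Fatty acid uptake and oxidation had a median of -0.09 (1 of 34 lower adjusted over the list alone, adjusted p = 0.0148, and adjusted p = 0.836 with an estimated correlation, range 4.17e-07 to 0.836). Hypoxia-inducible factor targets had 1 of 30 higher (4 adjusted over the list alone) and did not pass (adjusted p = 0.0655). None of the other 22 lists passed.

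At day 14, 89 features passed, 65 higher and 24 lower, and 29 of them differed at least 2-fold. Of the 89, 33 were called in the same direction under all 3 slide treatments, 26 higher and 7 lower. The differences are the same with the slide term and without the slide 1 arrays of day 0, so only their error and the treatment without the slide term bear on them. On slide 2 all day 14 arrays were dimmer than all day 0 arrays, so array brightness goes with day in this comparison. After normexp correction, 19 of the 89 were called. Within slide 2 alone limma called 1 feature, Ankrd37, a hypoxia-inducible factor target from a list fixed before the data were examined. On that slide 4675 features had an unadjusted p below 0.05. The count was 210 without the slide term and 35 without the slide 1 arrays of day 0. It was 3 without day 0 RNA sample 1, 14 without day 0 RNA sample 2, 34 without day 0 RNA sample 3, 36 without day 3 RNA sample 1, 167 without day 3 RNA sample 4, 26 without day 7 RNA sample 1, 219 without day 7 RNA sample 2, 168 without day 7 RNA sample 4, 24 without day 14 RNA sample 1 and 26 without day 14 RNA sample 2. Of the 13 selected genes called under all 3 slide treatments, 1 passed without day 0 RNA sample 1, 6 without day 0 RNA sample 2, 12 without day 7 RNA sample 1, 11 without day 14 RNA sample 1 and 12 without day 14 RNA sample 2. None turned sign, but neither did any of the 89, so this does not set these genes apart. Of the called features, 73.0% were higher, against 50.9% after quantile normalization, 48.5% with the series table and 80.0% without the slide 1 arrays of day 0.

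Day 7 against day 3 compares days on the same slide. Dbp rose by 3.25 ± 0.32 (limma adjusted p = 0.00146, n = 3 and 3), Per3 by 1.84 ± 0.26 (adjusted p = 0.00676) and Tef by 1.15 ± 0.15 (adjusted p = 0.00435), while Nfil3, a repressor in the clock, fell by 2.20 (adjusted p = 0.00966). Ciart, a clock repressor gene, was at least 6.10-fold higher, as no day 3 array was above background (adjusted p = 0.0268). Coq10b, which acts with coenzyme Q, rose by 1.58 and Amigo3, a neuronal adhesion gene, by 1.39. Ccl8, a chemokine, fell by 2.29 (adjusted p = 0.00568) and Cd209f by 1.49. Mmp3 was at least 1.81-fold lower and Mup1 at least 4.31-fold lower, since no day 7 array was above background for either. For each of these genes all 3 day 7 samples lay beyond all 3 day 3 samples, which the rule required of the largest rises and falls.

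Circadian clock genes had 6 of 17 members higher and 1 lower (11 and 2 adjusted over the list alone), with a median of 0.84 (adjusted p = 5.33e-06, and adjusted p = 0.122 with an estimated correlation, range over 29 alternatives 2.26e-08 to 0.122). Macrophage and monocyte markers had 2 of 26 lower (21 adjusted over the list alone), with a median of -1.20 (adjusted p = 7.91e-21, and adjusted p = 0.169 with an estimated correlation, range 2.72e-28 to 0.169). Under all 3 slide treatments 5 of the 6 higher and 1 of the 1 lower clock genes passed, and 0 of the 2 macrophage markers. In all, 150 features passed, 99 higher and 51 lower, and 54 of them differed at least 2-fold, 26 higher and 28 lower, while 75 were called under all 3 slide treatments. As both days lie on slide 1, these treatments give the same differences and change only their error. Within slide 1 alone, without the spread of the other slide, limma called 0 features, and 2627 had an unadjusted p below 0.05. The count was 28 without day 3 RNA sample 1, 231 without day 3 RNA sample 2, 43 without day 3 RNA sample 4, 33 without day 7 RNA sample 1, 63 without day 7 RNA sample 2, 268 without day 7 RNA sample 4, 73 without day 0 RNA sample 1, 81 without day 0 RNA sample 2 and 98 without day 14 RNA sample 2. Of the 15 selected genes called under all 3 slide treatments, 9 passed without day 3 RNA sample 1, 13 without day 3 RNA sample 4, 11 without day 7 RNA sample 2, 12 without day 7 RNA sample 1 and 14 or 15 without any other.

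Day 14 against day 7 covers the week at a stable oxygen level, and the days lie on different slides. The haemoglobin genes Hbb-b1 and Hbb-b2 rose by 3.11 ± 0.38 and 2.24 ± 0.37 (adjusted p = 0.00708 and 0.0177), and Alas2 rose by 2.08 ± 0.36 (adjusted p = 0.0194). The size for Hbb-b1 depends on the slide treatment. Its day 7 difference from day 0 was -1.59 with the slide term and 0.23 without the slide 1 arrays of day 0. Wnt4 fell by 2.08 ± 0.29 (adjusted p = 0.0101), Fmod by 2.60 ± 0.57 (adjusted p = 0.0377) and Ecrg4, a gene for a secreted peptide, by 3.67 ± 0.83 (adjusted p = 0.0408). Ecrg4 lay at -3.80 to -1.16 at day 14. The lowest level counted as above background on these arrays was -1.96 to -1.84 before slide adjustment, so the size for Ecrg4 is uncertain. Pdk4, which restrains pyruvate oxidation, fell by 1.69 (adjusted p = 0.0448) and Decr1 by 1.17, while Hspa1a rose by 1.18 (adjusted p = 0.0179) and Hmox1, which degrades haem, by 1.47, a gene whose other kept probe had a difference of 0.11. For Hbb-b1, Hbb-b2, Alas2, Wnt4, Fmod and Ecrg4 all 4 day 14 samples lay beyond all 3 day 7 samples after slide adjustment. The rule required this of the largest rises and falls, so it adds no evidence for genes chosen by that rule.

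Red blood cell and erythroid genes had 6 of 17 higher at day 14 than at day 7 (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.00169, and adjusted p = 0.47 with an estimated correlation, range over 27 alternatives 2.43e-05 to 0.47). Fatty acid uptake and oxidation had 3 of 34 lower (15 lower and 1 higher adjusted over the list alone), with a median of -0.55 (adjusted p = 9.9e-06, and adjusted p = 0.783 with an estimated correlation, range 2.29e-10 to 0.783). Under all 3 slide treatments 6 of the 6 red blood cell genes and 2 of the 3 fatty acid genes passed. In all, 509 features passed, 248 higher and 261 lower, and 187 of them differed at least 2-fold, 110 higher and 77 lower, while 252 were called in the same direction under all 3 slide treatments and 68 turned sign. The treatments without the slide term and without the slide 1 arrays of day 0 give the same differences for these days, and neither can tell day from slide. No comparison within a slide exists for these days. The count was 3754 without the slide term and 4186 without the slide 1 arrays of day 0. It was 2 without day 0 RNA sample 1, 5 without day 0 RNA sample 2, 262 without day 0 RNA sample 3, 309 without day 3 RNA sample 1, 985 without day 3 RNA sample 4, 65 without day 7 RNA sample 1, 89 without day 7 RNA sample 2 and 1210 without day 7 RNA sample 4. It was 242, 238, 224 and 192 without day 14 RNA samples 1, 2, 3 and 4. Of the 18 selected genes called under all 3 slide treatments, 0 passed without day 0 RNA sample 1, 1 without day 0 RNA sample 2, 12 without day 0 RNA sample 3, 15 without day 0 RNA sample 4 and 14 without day 3 RNA sample 1. Of the same 18, 7 passed without day 7 RNA sample 1, 9 without day 7 RNA sample 2, and 12, 12, 14 and 12 without day 14 RNA samples 1, 2, 3 and 4. Of the called features, 48.7% were higher, against 33.8% after normexp correction, 39.4% with probes above background on all arrays, 66.6% without the slide 1 arrays of day 0, 68.0% without the slide term and 72.3% with no filter.

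Over the 4 days, 3764 features passed the F-test, 674 of them with a difference of at least 2-fold from day 0. Ankrd37, Hspa1a, En1, Stard3, Dbp and Pcm1 had the smallest p. The count was 229 without day 0 RNA sample 1, 78 without day 0 RNA sample 2, 1601 without day 7 RNA sample 1 and 2297 without day 7 RNA sample 2. Several core genes of the hypoxia response and of fibre type did not pass against day 0 at any day, with Vegfa, a vascular growth factor, at 0.05, -0.11 and -0.07 at days 3, 7 and 14. Slc2a1, a glucose transporter, was at 0.28, 0.10 and -0.06, and Pdk1, an inhibitor of pyruvate dehydrogenase, at -0.16, -0.10 and -0.07. Myh7 and Myh2, the myosins of slow and of oxidative fast fibres, stayed within 0.06 to 0.18 at the 3 days, and myoglobin (Mb) within -0.12 to 0.00489. Egln3, Ddit4, Myh1, Myh4, Ppargc1a, Ucp3 and Trim63 did not pass at any day either. Other core genes lay higher in all day 7 samples than in all day 0 samples after slide adjustment. Bnip3 was at 8.04 to 8.31 against 7.35 to 7.64, but its other kept probe had a difference of -0.10. Fbxo32 was at 3.765 to 4.295 against 3.184 to 3.471, and Pdk4 at 8.485 to 8.711 against 6.834 to 7.849. Mstn, at low levels, was at -3.63 to -0.468 against -4.434 to -4.268.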

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

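The outlier test and the comparison of later days were fixed in advance, the spike-in and split tests were also chosen before their results were seen, and the slide, clock and erythroid tests were chosen after the pattern was seen. Some genes differed between later days by limma. Between day 3 and day 7, clock-linked genes rose: Dbp by 3.25, Per3 by 1.84, Tef by 1.15 and Cry2 by 0.84. Amigo3 also rose by 1.39, Ankrd37 by 0.91, Coq10b by 1.58 and the sterol transporter Stard3 by 0.80. Lower at day 7 were Ccl8 at -2.29, Cd209f at -1.49, Hspa1a at -1.40, Mup18 at -2.51, Mup19 at -1.61, Nfil3 at -2.20, the lipase gene Pnpla3 at -2.25 and Ppp1r3c at -1.15. The size for Mup18 is limited by day 7 levels near background. Ciart was at least 6.10-fold higher, Mmp3 at least 1.81-fold lower and Mup1 at least 4.31-fold lower; their fitted values of 4.72, -2.59 and -2.98 rest on a day with no array above background and do not measure a size.

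Between day 7 and day 14 the erythroid genes Alas2, Hba-a1, Hbb-b1, Hbb-b2 and Hbb-bt rose by 2.08, 2.03, 3.11, 2.24 and 1.96. The size for Hbb-b1 depends on the slide treatment. Ankrd2 rose by 0.92, Hmox1 by 1.47, Hspa1a by 1.18, and Rnu3b1 by 1.74. Sox1 was higher by 2.11, a call that turned sign without the slide term and whose other kept probe had -0.37. The genes that fell were Atp5l at -0.68, Decr1 at -1.17, Ecrg4 at -3.67, Fmod at -2.60, Pcm1 at -1.51, Pdk4 at -1.69, Pgm1 at -0.74, Vldlr at -1.03 and Wnt4 at -2.08. The size for Ecrg4 is limited by day 14 levels near background. The fitted values of En1 (2.26), Itga5 (2.09), Fam227b (-2.58) and Gria4 (-1.83) passed too, but no day 14 array was above background for these genes, and for En1 no day 7 array either, so they do not measure a size, and that of Itga5 turned sign without the slide term.

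Of 230 groups of 4 RNA samples tested by Dixon's ratio over 115 genes, 12 held a sample apart from the other 3, about the number chance gives at 1 in 20. At day 14 these were Acvr1c in sample 3 (-3.34, others -4.50 to -4.42), Dgat2l6 in sample 1 (-3.14, others -4.30 to -4.19), Fam227b in sample 3 (-3.97, others -4.98 to -4.88), Fxyd7 in sample 3 (-2.57, others -1.44 to -1.36), Mmp3 in sample 2 (-3.40, others -4.22 to -4.10) and Slc22a2 in sample 1 (-2.94, others -4.08 to -3.93). Tnni1, the slow troponin I, was at 7.78 in sample 4 (others 7.27 to 7.35) and Zfp219 at -1.76 in sample 4 (others -2.39 to -2.30). At day 0 these were Ciart in sample 2 (-1.32, others -4.57 to -4.06), Fmod in sample 4 (2.51, others 3.88 to 4.00), Pla2g5 in sample 2 (-3.48, others -4.39 to -4.27) and Ramp2 in sample 1 (4.23, others 4.03 to 4.05). Several of these values lie below background, and none was left out.

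The day 0 arrays on slide 1 stood apart from all others. A slide difference carried by all slide 1 arrays alike could give slopes near 1 for the day 3 and day 7 arrays on the slide difference of the day 0 RNA samples. The slopes were 0.125 to 0.629. Biology shared by day 3 and day 7 would also move these slopes, so the test cannot tell. Across features the slide term correlated at -0.524 with the day 3 and -0.488 with the day 7 differences from day 0. Both rest on the same 2 day 0 arrays of slide 1. Labelling or hybridization of these 2 arrays could have differed, and their spike-in levels were 2.91 and 3.11. They lay inside the 2.57 to 3.62 of the other slide 1 arrays through 1 array alone, and below the other 5, which start at 3.21, so the range set in advance decides nothing and this stays open.

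Clock genes differed between day 7 and day 3. Clock genes driven through E-boxes and D-boxes had a median of 1.13 and those repressed by Nr1d1 and Nr1d2 a median of -0.952, of which Nfil3 alone of 3 passed (-2.20). Muscles taken at another time of day could give opposite arms, but the test was written after clock genes of both arms had been seen, and 1 called gene in the second arm decides nothing. Another makeup of cell types also stays open, since macrophage markers had a median of -1.20 between these days. The labels give no collection time.

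Erythroid genes were higher at day 14. More blood in the samples could raise them, and the neutrophil list then should rise too, but it differed by -0.333 (exact permutation p = 0.343, adjusted p = 0.457, n = 4 and 4), so the test cannot tell. The red blood cell list differed by 0.586 (exact permutation p = 0.0286, adjusted p = 0.114). That p is the smallest this test can give with 4 against 4 samples, so 1 list alone could not pass after adjustment. The day 14 value does not cross slides by design, and on slide 2 arrays alone the mean of all 17 genes of the list was higher by 0.587 ± 0.0943 (SE), which a difference between slides cannot give.

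Splits of the RNA samples into other groups asked whether chance could give the counts. The real groups gave the highest count of 35 splits for day 3 (1349, highest other 0) and day 7 against day 0 (5263, highest other 17). The same held for day 14 against day 0 (89, highest other 20) and day 14 against day 7 (509, highest other 0). Over the 4 days the real groups gave the highest count of 100 splits (3764, highest other 542). A share of 1 of 35 is the smallest that 35 splits can give. The RNA samples regrouped in these splits were not all run on the same slides, so they are not interchangeable, and chance is not excluded. For day 7 against day 3 the 10 splits are too few (1 of 10, 150, highest other 1). The other splits took the array correlation from 1500 features, and with it the real counts were 1349, 5271, 90, 479 and 3772, and 150 for day 7 against day 3. The splits do not test the slide difference.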

How the results depend on the processing

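The alternative without the slide 1 arrays of day 0 was added after seeing the data, and all others were fixed before. The cause of the changes below was not tested.

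For day 3 against day 0 the count of 1349 became 190 at least 2-fold, 504 with no slide term, 0 within slide 1, 3492 after normexp, 403 with no filter on dim probes, 2615 with probes above background on all arrays, 2189 with trend and robust, 2075 without the slide 1 arrays of day 0 and 736 with only the 2 days compared. Leaving out 1 RNA sample gave 4 to 1713. For day 7 against day 0 the count of 5263 became 695 at least 2-fold, 2665 with no slide term and 2093 within slide 1, and leaving out 1 RNA sample gave 25 to 5800. For day 14 against day 0 the count of 89 became 29 at least 2-fold, 210 with no slide term, 1 within slide 2, 21 with the replicate block, 23 after normexp, 214 after quantile normalization, 674 with the series table, 17 with no filter, 416 above background on all arrays, 457 with trend and robust, 35 without the slide 1 arrays of day 0 and 47 with only the 2 days. Leaving out 1 RNA sample gave 3 to 219.

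For day 7 against day 3 the count of 150 became 54 at least 2-fold, 80 with no slide term, 0 within slide 1, 44 with the replicate block, 730 after normexp, 44 with no filter, 445 above background on all arrays, 392 with trend and robust and 2 with only the 2 days, and leaving out 1 RNA sample gave 28 to 268. For day 14 against day 7 the count of 509 became 187 at least 2-fold, 3754 with no slide term, 1146 with the replicate block, 4160 after normexp, 808 with the series table, 285 with no filter, 1660 above background on all arrays, 1265 with trend and robust and 4186 without the slide 1 arrays of day 0, and leaving out 1 RNA sample gave 2 to 1210. The replicate numbers do not pair the RNA samples across days: 19 pairs with the same number correlated at -0.152 to 0.169 and other pairs at -0.203 to 0.181. The fit on only these 2 days and the fit within 1 slide cannot be run for day 14 against day 7, and the F-test was not run within 1 slide or on 2 days. Over the 4 days the count of 3764 became 674 at least 2-fold, 6290 after normexp and 1450 with no filter, and leaving out 1 RNA sample gave 78 to 4724.

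Without the slide 1 arrays of day 0 these genes turned sign at day 3: Fam13c -0.080, Sox1 0.056, Dtx3 0.60, Pkm 0.084, Uqcrc1 0.0033, Tnni1 0.19, Mylpf 0.28, Map1lc3a 0.067, Sqstm1 0.11, Mef2d 0.15, Tie1 0.18, Des 0.22, Cd3e -0.54, Shmt2 0.026, Rps20 -0.010 and Lss 0.14. At day 7 they were Itga5 0.64, Map1lc3a 0.023, Sqstm1 0.19, Mef2d 0.078, Tie1 0.18, Cd3e -0.64, Hbb-b1 0.23, Sptb 0.065, Igf2 0.23, Nr1d1 0.79, Calr 0.10 and Psmc4 0.12. With no slide term Dtx3 (0.060) and Mylpf (0.042) turned at day 3, and Sqstm1 (0.022), Cd3e (-0.40), Nr1d1 (0.38) and Psmc4 (0.028) at day 7. For day 14 against day 7, Sox1 (-0.010), Itga5 (-0.85) and the list of cytosolic ribosomal proteins (0.0782) turned with no slide term and without the slide 1 arrays of day 0. With the mean of all probes Gstm1 (-0.12) and Mvk (-0.11) turned at day 7.

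Among lists, at day 14 normexp turned glycolysis and glycogen metabolism (-0.0937), oxidative phosphorylation (0.0336, by its camera direction) and proteasome subunits (-0.0422). Quantile normalization turned cytosolic ribosomal proteins for day 7 against day 3 (-0.00311), and leaving out day 3 RNA sample 4 turned the camera direction of fatty acid uptake and oxidation at day 3, while its median kept its sign (0.298 against 0.07).

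For values of named genes, 218 stayed the same, 108 weakened, 4 strengthened and 8 turned with no slide term, against 193, 135, 0 and 0 within 1 slide, and 212, 92, 4 and 30 without the slide 1 arrays of day 0. Leaving out 1 RNA sample kept 3945, weakened 747 and strengthened 40. The other alternatives turned 2 gene values in all and weakened 0 (above background on all arrays) to 84 (no filter). For lists an estimated correlation weakened 51 and left 114 the same, and fry weakened 32 and left 130 the same. Those left the same include lists that camera had not called. Of the lists called by camera, fry also called 2 of 4 at day 3, 5 of 10 at day 7 and 3 of 10 at day 14 against day 0. Between later days it also called 4 of 15 for day 7 against day 3 and 5 of 12 for day 14 against day 7. No list call by camera was kept with an estimated correlation.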

Other observations

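The tests in this part were chosen after the results were seen, apart from the lists and the settings, which were fixed before. The plan named list tests for the 3 differences from day 0 and did not name those between later days. Myh4, the myosin of the fastest fibres, had the largest SD of the 115 selected genes at days 0, 7 and 14 though not at day 3, with log2 levels of 4.54 ± 1.97 (SD) at day 0, 9.64 ± 0.19 at day 3, 8.11 ± 3.08 at day 7 and 4.26 ± 1.87 at day 14 (n = 4, 3, 3 and 4). Its differences from day 0 of 5.16 ± 1.57, 3.63 ± 1.57 and -0.22 ± 1.26 (SE) did not pass (limma, adjusted p = 0.0684, 0.113 and 0.941). The spread may come from neighbouring fast muscle in some samples or from fibres of the soleus itself, and for Myh4, day 3 against day 0, the adjusted p was 0.0476 with only the 2 days compared and 0.0154 to 0.142 over all alternatives that keep every RNA sample.

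Further lists passed by camera for day 7 against day 3 without a call by an estimated correlation. Oxidative phosphorylation had a median of 0.29 (0 of 76 members past the threshold and 0 adjusted over the list alone, adjusted p = 3.36e-12, and adjusted p = 0.468 with an estimated correlation, range over 29 alternatives 1.13e-17 to 0.468) and fatty acid uptake and oxidation 0.43 (0 of 34 members past the threshold, 13 higher adjusted over the list alone, adjusted p = 2.26e-07, and adjusted p = 0.468 with an estimated correlation, range 1.89e-11 to 0.468). Extracellular matrix and fibroblast genes had a median of -0.56 (0 of 34 members past the threshold, 4 lower adjusted over the list alone, adjusted p = 1.51e-11, and adjusted p = 0.376 with an estimated correlation, range 3.11e-17 to 0.376), and cell cycle genes -0.66 (0 of 23 members past the threshold and 0 adjusted over the list alone, adjusted p = 4.36e-05, and adjusted p = 0.418 with an estimated correlation, range 7.07e-09 to 0.418). The other lists that passed had medians of 0.41 (red blood cell and erythroid genes), -0.60 (adipocyte markers), -0.38 (satellite cell and myogenic genes), 0.30 (citric acid cycle and pyruvate dehydrogenase), -0.19 (heat shock genes), -0.22 (interferon stimulated genes), 0.12 (cytosolic ribosomal proteins, turned by quantile normalization), 0.11 (proteasome subunits) and -0.13 (cholesterol synthesis genes). Their adjusted p was 1.39e-05 to 0.0118 by camera and 0.149 to 0.682 with an estimated correlation, and 8.09e-10 to 0.965 over 29 alternatives. Of the 33 lists, 15 passed here by camera, 0 with an estimated correlation and 4 by fry.

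For day 14 against day 7, 12 lists passed by camera, 0 with an estimated correlation and 5 by fry. Tendon and connective sheath markers had a median of -1.56 (2 of 11 lower, 6 adjusted over the list alone, adjusted p = 0.00152, and adjusted p = 0.783 with an estimated correlation, range over 27 alternatives 1.04e-05 to 0.783). Heat shock genes had 2 of 24 higher (3 adjusted over the list alone, adjusted p = 0.00152, and adjusted p = 0.47 with an estimated correlation, range 0.00024 to 0.47). Cytosolic ribosomal proteins were at -0.12 (adjusted p = 0.0332, and adjusted p = 0.831 with an estimated correlation, range 8.13e-05 to 0.831) and turned to 0.0782 without the slide term. The call of this list was kept in 13 of the 27 alternatives. The other lists that passed had medians of 0.51 (macrophage and monocyte markers), 0.37 (interferon stimulated genes), 0.31 (slow fibre genes), 0.24 (pericyte and smooth muscle markers), -0.20 (oxidative phosphorylation), -0.30 (citric acid cycle and pyruvate dehydrogenase) and -0.18 (proteasome subunits). Their adjusted p was 0.00152 to 0.0239 by camera and 0.47 to 0.831 with an estimated correlation, and 2.31e-07 to 0.831 over 27 alternatives. Without the slide term the calls of slow fibre genes (adjusted p = 0.237), pericyte markers (0.143), oxidative phosphorylation (0.196) and proteasome subunits (0.0547) ended.

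Of the 115 genes looked at, 28 have another kept probe, and in 35 of 170 pairs of probe and comparison the other probe had the opposite sign. Hmox1, Pcm1 and Sox1 are examples, so their values may belong to 1 transcript form or 1 probe, and without the slide 1 arrays of day 0 the Pcm1 difference at day 7 was 1.30.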
